A study of Mus musculus with 66 samples.

How the data were processed

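The 66 samples of the series were chromatin immunoprecipitation, CATCH-IT and input libraries from mouse. Of these, 41 belonged to the 14 groups compared in the 7 tables, and 20 were inputs. HA immunoprecipitation and embryonic NeuN-positive samples have no table among those used and were not analysed here. Per the submitters' processing notes, Bowtie 0.12.7, bedtools 2.16.2 and the mouse build mm9 were used. The tool that called the regions is not given in the sources used here. The control group at 30 min had 4 libraries in the labels, one a repeat of the first, and 3 values per region.

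Each table listed regions of at least 200 bp that the authors called as different between 2 groups. Region lengths grew in steps of 20 bp. Per the file headers, each region had the authors' normalised read counts of the libraries of each group, packed in one cell without library names. The group mean of those values, a coverage signal in the region, was also deposited, and it equalled the mean of the packed values within 0.02 in 100% of regions. The authors deposited a ratio of each group mean to input, infinite where input was 0. They also deposited a log2 fold change of treated over control, infinite where one mean was 0. The authors' p-value and adjusted p-value per region were deposited and used as they stood. The smallest absolute log2 fold change was 1.59 to 1.60 in every table, so that changes under about 3-fold were not listed and a region missing from a table was not shown to be unchanged. The authors also deposited a window p, whose test is not given here, and it was at most 9.99e-05 in every table. Counts of regions by adjusted p are therefore counts among regions that already had a low window p on the same libraries. Normalisation was done by the authors within each table. The name of the CATCH-IT table points to normalisation by library and to a duplicate setting of 6, the method is otherwise not given in the sources used here, and levels were never compared across tables. Columns of per-sample values left unused numbered 0.

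Depth per library was read from the packed values, since library totals were not used here. In the H3.3 culture, CATCH-IT and NeuN-negative tables the low values of every library were whole multiples of one step within 0.1, for 100% of low values, and the step is what 1 read was worth. No step could be found for the H3.1/2 libraries or for the enriched NeuN-positive libraries. Because the listed regions had been chosen on these libraries, no new test of counts per region was run. Intervals on shares cover counting of regions only, and neighbouring regions are not independent.

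The share of gained regions per table was given with an exact (Clopper-Pearson) 95% interval and a two-sided exact binomial test against an even split. Shares were compared between 6 pairs of tables, and promoter, gene body and intergenic shares between gained and lost regions, with two-sided Fisher's exact tests. Overlap of at least 1 bp was compared with 1000 random placements per pair on the same chromosomes (one-sided permutation test). Agreement in direction was tested where at least 10 regions overlapped. Occurrence of 18 gene lists was compared by one-sided Fisher's exact tests with the 9790 genes named at a promoter or gene body in any table, and direction where a list had at least 3 regions (44 tests, two-sided). Because 9124 of those genes had a CATCH-IT region, the occurrence test says little for CATCH-IT, and list sizes in it are of members with a region in any table. All families were adjusted after Benjamini and Hochberg, and 0.05 was the threshold. Adjusted p of single genes over a list alone was not computed, because the tables hold listed regions only. The tests of overlap, of differences in share and of gene lists against random lists of the same gene lengths were tried on simulated data. The Fisher's exact tests of gene lists, of promoter, gene body and intergenic shares and of agreement in direction were not. Lists were of the size of H3.3 at 5 hr and NeuN-positive nuclei, 2309 regions together. In 100 simulations p was under 0.05 in 2% for overlap and in 5% for differences in share. Planted effects of 20 overlaps or of 20 points in share were recovered in 100%, and smaller ones were not simulated. Simulated gene lists drawn for the NeuN-positive table over 22176 genes gave 3%, and lists of long genes 1%.

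The gene lists were immediate-early genes, late-response activity genes, glutamate receptors, GABA and glycine receptors, postsynaptic scaffold and signalling, presynaptic release machinery, adhesion and axon guidance, voltage-gated ion channels, activity-linked transcription and chromatin regulators, genes of H3.3 and its chaperones, neuron, interneuron, astrocyte, oligodendrocyte lineage, microglia and endothelial or pericyte markers, housekeeping genes, and olfactory and vomeronasal receptors. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per table, one region per gene at a promoter or gene body, and named the 6 gained and 6 lost genes with the smallest authors' adjusted p, the 2 members of each list with the smallest adjusted p, and immediate-early genes listed in any KCl table. It named 25, 27, 31, 4, 50, 35 and 31 regions in the tables from 30 min to NeuN-negative nuclei. Predicted genes were passed over, and clone-named or small RNA entries are not named. Some genes that the rule picked are not reported here. Other list members are named to complete a count and were chosen after their values were seen.

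Positions are 1-based in mm9 as deposited. Exons, introns and UTRs were taken from GENCODE vM1 on the same build, and current symbols from a RefSeq gene table on GRCm38.p6, used for names only. Some annotated genes are very long, as Fgfr2, and some regions were assigned by the authors to a gene far away, as for Rbfox1. Distances to genes are from GENCODE. After the data were seen, the authors' ratios to input of both groups were compared for regions where both were finite. A region on mitochondrial DNA was left out of the named genes. GC content was read from the genome sequence. Alternatives were stricter adjusted p (0.01, or 0.001 for CATCH-IT), absolute log2 fold change over 2, a higher group mean of at least 20, merging within 1000 bp, chromosomes 1 to 19 only, each library left out with the 3-fold limit kept, other definitions of overlap, placement within position class, 10000 random gene lists matched in 20 length classes, promoters only and 1 region per gene. Alternatives chosen after seeing the data were an adjusted p of 0.05 or less and CATCH-IT regions over 380 bp only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used with a fixed seed of 1.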

Results

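Chromatin from mouse neurons was profiled to ask where the histone variant H3.3 is gained or lost after depolarisation and after enriched housing. H3.3 is the form of histone H3 that is placed into chromatin outside DNA replication, while H3.1 and H3.2 (H3.1/2) are placed mainly during replication. Cortical neurons from mouse embryos were kept for 8 days in vitro and were exposed to KCl, which depolarises the membrane, or to a control treatment. H3.3 was immunoprecipitated after 30 min, 2 hr and 5 hr, and H3.1/2 after 5 hr. CATCH-IT, which captures newly made histones through a metabolic tag and so reads histone turnover, was run after 5 hr. Nuclei from the hippocampus of 7 week old mice were sorted into neurons (NeuN-positive) and other cells (NeuN-negative), and H3.3 was immunoprecipitated. The mice had 4 weeks of enriched housing or were normally housed.

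The 7 deposited lists held regions that the authors called as gained or lost, each with a normalised read count per library. Every group had 3 libraries in its list except the NeuN-positive groups, which had 2 each. All values for single regions are therefore means ± SD over 3 libraries (n = 3), or over 2 libraries (n = 2) in NeuN-positive nuclei. The normalised count that stood for 1 read ran from 0.758 to 1.36 over the 18 libraries of the H3.3 culture lists, from 0.542 to 2.64 over NeuN-negative libraries and from 0.316 to 2.72 over CATCH-IT libraries, so depth differed most in CATCH-IT. Nothing in the labels says that libraries of a group came from separate cultures or animals, so the authors' p-values cover at most the spread between these libraries. The tests of shares, overlaps and gene lists count regions or genes and do not measure spread between libraries. In the 30 min, 2 hr, CATCH-IT and NeuN-negative lists all libraries of one group shared a sequencing lane and all libraries of the other group another, so within-lane values could not be had. By lane number, the 5 hr H3.3 list had 3 lanes that each held 1 KCl and 1 control library, and the 30 min and 2 hr lists had none. Levels relative to input are the ratios that the authors deposited, and how often they moved the same way as the count was examined after the data were seen. These ratios hold the count on which a region was listed, so the listing alone favours a move the same way. The labels give 1 input library per group for H3.3 in culture and in NeuN-negative nuclei, 2 in NeuN-positive nuclei and 3 for CATCH-IT. No input is labelled for H3.1/2. Where input was 1 library, the ratio of a single region holds no measure of spread in input.

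After 30 min of KCl, H3.3 fell at 359 regions and rose at 91 regions with an authors' adjusted p of 0.05 or less, of 457 listed. Among the regions that fell were those at Usp28, a deubiquitinase, Ncor1, a corepressor of nuclear receptors, Lrp6, a Wnt co-receptor, and Bmi1, a Polycomb subunit. The Usp28 count went from 11.6 ± 0.164 in control to 1.33 ± 0.672 in KCl, and the Ncor1 count from 15.6 ± 2.96 to 2.94 ± 0.307. The Lrp6 count went from 15.9 ± 2.79 to 3.29 ± 0.774, and the Bmi1 count from 17.2 ± 2.64 to 3.93 ± 0.410. Sft2d3 also fell. H3.3 rose at Dnase2b, an acid endonuclease, from 1.68 ± 1.11 to 11.8 ± 1.22, and at Uggt1, which checks glycoprotein folding, from 2.57 ± 2.19 to 12.5 ± 2.17. Cdh11, a cadherin, and Zfpm2, a cofactor of GATA factors, rose as well. Zfp536 was listed as lost and Adra1a, an adrenergic receptor gene, as gained, but relative to input in the authors' deposited table they differed little, with 2.88 in control and 2.52 in KCl for Zfp536 and 1.48 and 1.82 for Adra1a. The log2 fold changes of Usp28, Ncor1 and Dnase2b in the authors' deposited table were -3.12, -2.41 and 2.81, each with an adjusted p of 0.00552. In mm9 the Usp28 region was on chromosome 9 from 48807961 to 48808160, in an intron and near a gene start, and the Dnase2b region on chromosome 3 from 146104381 to 146104600, in an intron. The Bmi1 region, on chromosome 2 from 18597541 to 18597780, lay 865 bp upstream of the annotated gene.

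Genes of adhesion and axon guidance were the most frequent group at 30 min, with 12 listed of the 57 members that had a region in any table, against 1.94 by chance (Fisher's exact test, adjusted p = 4.57e-05). Of these, 9 had only lost regions, among them Ptprd, a synaptic receptor phosphatase that went from 14.3 ± 2.43 to 3.19 ± 1.87, and Cntnap4, Cdh8 and Robo2. Cdh11 and Ephb1 had only gained regions and Cdh2 had both. All 3 listed members of the presynaptic release machinery fell, Snap25 from 14.8 ± 4.74 to 3.53 ± 1.27, Erc1 from 11.9 ± 0.556 to 2.83 ± 1.29, and Syt1. Only 17.2% of regions at other genes were gained, so the fall of all 3 does not set this group apart. Of 4 postsynaptic genes, Dlg2, Homer2 and Magi1 fell and Magi2 rose. Gabbr2, a subunit of GABA receptors, and Kcnd3, a potassium channel, also fell. Gabrb1 was listed as lost, yet its level relative to input in the authors' deposited table was 1.58 in control and 1.94 in KCl, the other way. The neuron marker Celf5 and the interneuron marker Reln fell, and the endothelial marker Pecam1 rose from 2.79 ± 1.45 to 11.03 ± 0.661. H3f3a, which encodes H3.3, was listed as lost with 14.9 ± 4.86 in control and 4.10 ± 1.69 in KCl, and the authors' deposited table gave it an adjusted p of 0.0592 and 1.69 and 1.28 times input. No immediate-early, late-response or glutamate receptor gene was listed at 30 min. These lists had 10, 12 and 21 members with a region in any table, and 334 of 9790 genes were named at 30 min. Such zeros therefore carry little information. None of the group counts at 30 min passed when set against random lists of the same gene lengths, where 4.94 adhesion genes came by chance (permutation adjusted p = 0.151).

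Of the 457 regions at 30 min, 20.1% were gained (exact 95% interval 16.55 to 24.1, exact binomial p = 1.58e-39). The median lost region had 2.29 times the input level in control and 0.63 times in KCl. Of 444 regions with finite ratios to input, 96.2% moved the same way relative to input as in count, and 83.3% by at least 2-fold. Gained regions were more often intergenic than lost ones, 37.0% against 22.5% (Fisher's exact test, adjusted p = 0.0293). Lane and treatment coincided in this comparison. When the list was split into 3 parts by GC content, most regions were lost in each part, with 29.6% gained in the lowest and 13.9% in the highest.

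**Figure D1:**
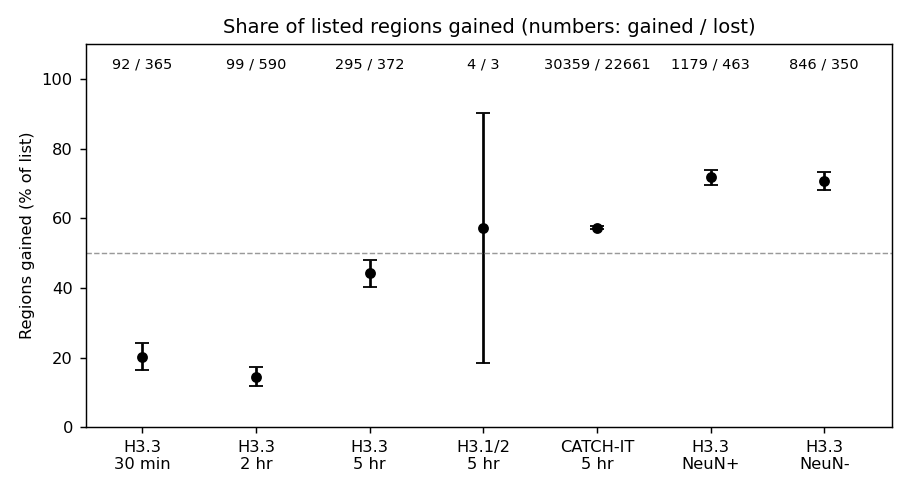
Percent of listed regions that were gained, for each of the 7 lists, with exact 95% binomial intervals; the numbers above give gained and lost regions, and the dashed line marks an even split. The 30 min and 2 hr lists lay at 20.1% and 14.4%, and both hippocampal lists above 70%.

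After 2 hr of KCl, H3.3 fell at 588 regions and rose at 98 regions with an authors' adjusted p of 0.05 or less, of 689 listed. It fell at Arl5b, a small GTPase, from 21.1 ± 3.13 to 5.66 ± 2.73, at Pcgf3, a Polycomb protein, from 12.3 ± 0.149 to 1.88 ± 0.766, and at Senp5, a SUMO protease, from 18.3 ± 0.931 to 4.62 ± 2.83. It also fell at Bnip2, Pkhd1l1 and Kbtbd11. It rose at Iqsec1, an exchange factor for Arf GTPases, from 1.24 ± 1.25 to 10.3 ± 0.541, at Slc2a1, a glucose transporter, from 2.89 ± 1.13 to 13.2 ± 0.916, and at Nkain1, Rad54l2 and Shroom3. The log2 fold changes of Arl5b and Iqsec1 in the authors' deposited table were -1.90 and 3.05, with adjusted p of 0.00467 and 0.01003. The Arl5b region was on chromosome 2 from 15001681 to 15002040 (mm9), in the 3′ UTR, and the Iqsec1 region on chromosome 6 from 90626721 to 90626920, in a coding exon. The Slc2a1 region, on chromosome 4 from 118780101 to 118780320, lay 996 bp upstream of the gene.

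Voltage-gated calcium channel genes were split at 2 hr, with the N-type channel gene Cacna1b up from 2.41 ± 2.158 to 12.6 ± 1.71 and Cacna1c, Cacna1d, Cacna1e and Cacna2d1 down. That made 20.0% of channel regions gained against 11.2% at other genes, a difference that did not pass. The glutamate receptor gene Grin2b fell from 13.8 ± 1.41 to 3.69 ± 2.59, and Smarca2, a remodelling ATPase, from 12.2 ± 2.32 to 3.33 ± 3.09. Per1 was the only immediate-early gene listed and fell from 13.7 ± 0.495 to 4.11 ± 0.435. Gabrg3, Erc2 and the astrocyte markers Gpc5 and Slc4a4 fell. The interneuron marker Reln fell in count, and from 2.65 to 1.81 times input in the authors' deposited table. Among postsynaptic genes Dlg2 fell from 14.7 ± 2.80 to 3.44 ± 1.84 in count, although input was 0 there in KCl, and Dlgap1 had both a gained and a lost region. Adhesion and axon guidance genes again came up 12 times among 57 (2.52 by chance, Fisher's exact test, adjusted p = 0.000342), with Dscam and Negr1 among the 7 that only fell. The voltage-gated channel count of 5 among 43 did not pass (adjusted p = 0.333), and the adhesion count did not pass against random lists of the same gene lengths (permutation adjusted p = 0.307).

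At 2 hr 14.4% of regions were gained (exact 95% interval 11.8 to 17.2, exact binomial p = 5.88e-86), and 46.5% of gained against 29.2% of lost regions were intergenic (Fisher's exact test, adjusted p = 0.00694). Of 669 regions with finite ratios to input, 95.7% moved the same way relative to input and 81.8% by at least 2-fold. Lane and treatment coincided here too. The share gained was 3.91% in the lowest and 27.1% in the highest part by GC content.

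After 5 hr of KCl, 3 immediate-early genes, which neurons transcribe within minutes of activity, were listed as gained and none as lost. H3.3 rose at Fosb from 8.79 ± 0.622 to 26.6 ± 2.77 and at Egr1 from 4.88 ± 0.871 to 18.8 ± 3.02. At Fos, whose adjusted p did not pass, the counts were 4.52 ± 1.42 in control and 14.7 ± 2.85 in KCl. The log2 fold changes of Fosb, Egr1 and Fos in the authors' deposited table were 1.60, 1.94 and 1.70, with adjusted p of 0.0347, 0.0399 and 0.108. The Fosb region was on chromosome 7 from 19890721 to 19891100 (mm9), in an intron. The Egr1 region, on chromosome 18 from 35025421 to 35025680, lay 783 bp downstream of the annotated gene, and the Fos region, on chromosome 12 from 86819001 to 86819200, lay 778 bp downstream. The 3 listed members of 10 compared with 0.462 by chance (Fisher's exact test, adjusted p = 0.129) and with 0.247 in random lists of the same gene lengths (permutation adjusted p = 0.151), so neither count passed after adjustment.

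H3.3 fell at Smarcc1, a subunit of the SWI/SNF remodelling complex, from 33.05 ± 2.33 to 9.53 ± 5.02, and at Macroh2a1, which encodes the histone variant macroH2A1, from 20.3 ± 1.32 to 5.96 ± 2.61. It also fell at Rgmb, Ephx1 and Lims1, and it rose at Shroom3, Macrod1, Efs and Arhgap31, the latter from 5.96 ± 0.172 to 21.0 ± 4.09. The authors' deposited table gave Smarcc1 a log2 fold change of -1.79 with an adjusted p of 0.00606, and gave the others adjusted p from 0.0347 to 0.0462. The Smarcc1 region was on chromosome 9 from 110108061 to 110108460 (mm9), in an intron. Of the 667 listed regions 20 had an adjusted p of 0.05 or less, 11 gained and 9 lost, so the remaining genes are given by value. The growth factor gene Bdnf was listed as lost, with 15.8 ± 1.49 in control and 4.72 ± 1.54 in KCl, as was the transcription factor gene Mef2c. Camk2a, a kinase of the postsynaptic density, was listed as gained with 7.24 ± 2.30 and 21.9 ± 3.27, while the authors' deposited table gave 1.13 and 1.38 times input. The glutamate receptor genes Gria1, Grik3 and Grm5 were listed as lost and Grik4 as gained.

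**Figure D2:**
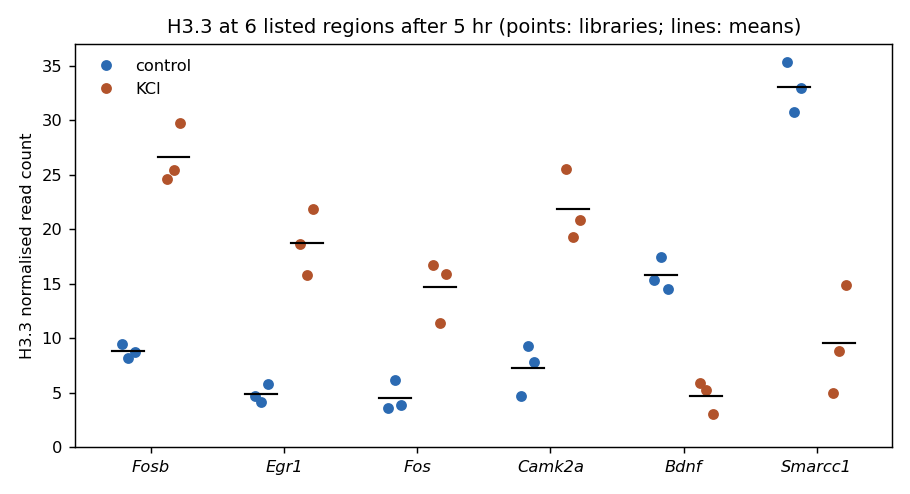
H3.3 normalised read count per library at 6 listed regions after 5 hr of control treatment or KCl, with lines at the group means (3 libraries each). At Fosb the KCl libraries lay between 24.6 and 29.8 and the control libraries between 8.20 and 9.44; Fos, Camk2a and Bdnf had adjusted p above 0.05.

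By group, 6 of 24 postsynaptic genes (Fisher's exact test, adjusted p = 0.0130) and 9 of 43 voltage-gated channel genes (adjusted p = 0.00384) had a region at 5 hr, none with an authors' adjusted p of 0.05 or less. Camk2a, Dlgap2, Prickle1 and Shank2 were listed as gained and Dlg2 and Dlgap1 as lost, while 5 channel genes were only gained, 3 only lost, and Kcnma1 both. Against random lists of the same gene lengths neither count passed (permutation adjusted p = 0.171 for both). Other groups were sparse. Syn3 and Cplx2 were listed as gained and Rims2 as lost among presynaptic genes, and 4 adhesion genes as gained and 3 as lost. Hdac4 and the astrocyte marker Gpc5 were listed as gained, as was a region assigned to the neuron marker Rbfox1 that lay 870455 bp upstream of the annotated gene, and Gabrb1 and the housekeeping gene Ywhaz were listed as lost. Listed regions split to 44.2% gained (exact 95% interval 40.4 to 48.1, exact binomial p = 0.00322), which did not pass without the second KCl value (exact binomial p = 0.0697) or the third (p = 0.12), with no difference in promoter, gene body or intergenic shares that passed. The split turned with GC content, from 10.5% gained in the lowest part to 77.4% in the highest, and Fosb, Egr1 and Camk2a lay at 53.2%, 52.3% and 56.3% GC against 45.3% for Smarcc1 and 37.5% for Bdnf. It also turned to 55.0% among the 20 regions with an adjusted p of 0.05 or less. Relative to input 99.7% of the 667 regions moved the same way as in count, and 93.6% by at least 2-fold.

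H3.1/2 after 5 hr gave 7 regions, 4 gained and 3 lost. The Myc region, at the promoter of this growth-control transcription factor gene, rose from 8.20 ± 2.18 to 25.8 ± 1.05, and Mrps35, a mitochondrial ribosomal protein gene, from 5.93 ± 1.23 to 20.1 ± 2.96. A region in an intron of the very long annotated Fgfr2 gene fell from 24.7 ± 1.11 to 7.60 ± 1.61. It lay 2.03e+06 bp from the gene start that the authors assigned, so its link to Fgfr2 rests on the annotated span. An intergenic region on chromosome 13 from 19987001 to 19987220 (mm9) rose as well, while Ankrd13d and 2 lost intergenic regions had adjusted p of 0.0808 to 0.126 in the authors' deposited table. The Myc region was on chromosome 15 from 61819521 to 61819780, in a coding exon. None of the 18 gene lists tested had a member with an H3.1/2 region, but at most 0.0572 members per list came by chance, so these zeros carry no information. The same holds for the 0 overlaps with H3.3 regions of the same time point, where random placement also gave 0. The share gained of 57.1% had an exact 95% interval of 18.4 to 90.1, and its difference of 12.9 points from H3.3 did not pass (Fisher's exact test, adjusted p = 0.706).

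CATCH-IT after 5 hr gave 53020 regions, 30359 gained and 22661 lost, over 9124 genes. Many genes had both, and values here are of the one region with the smallest adjusted p. Rasgrf1, an exchange factor for Ras, had 2 gained regions and none lost, and the first had 16.46 ± 3.17 in KCl and 0 in all control libraries. Homer1, an immediate-early scaffold gene with 2 gained and 2 lost regions, had a gained one with 12.5 ± 8.21 in KCl, and Bdnf, with 3 gained and 1 lost, one with 9.18 ± 6.63, both listed at 0 in control. Erbb4, a neuregulin receptor gene with 10 gained and 4 lost regions, had a lost one with 13.4 ± 14.4 in control, and Gapdh a single lost one with 10.1 ± 7.96, both listed at 0 in KCl. Apart from Rasgrf1, these regions had an SD that was large next to the mean. In KCl libraries 1 read stood for 1.34, 0.533 and 2.72, and in control libraries for 0.316, 1.39 and 1.18. Equal read numbers therefore also give a large SD, which need not be spread in reads between libraries. The Rasgrf1 region was on chromosome 9 from 89895261 to 89895660 (mm9), in a coding exon, and the Bdnf region on chromosome 2 from 109553241 to 109553620, in an intron. The Bdnf mean and SD are those of 6 reads in each of the 3 KCl libraries, and the region was 380 bp long. It may thus be a stack of reads at a single position, as treated below.

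CATCH-IT regions, gained and lost, lay in genes of every group. By group, counted over all members of each list and with the mean of random lists of the same gene lengths in brackets, 57 of 62 adhesion genes (55.2), 42 of 44 channel genes (37.3), 25 of 31 presynaptic (21.8), 24 of 27 postsynaptic (21.2), 21 of 26 glutamate receptor (20.9) and 17 of 20 GABA and glycine receptor genes (15.5) had a region. So had 20 of 36 activity-linked regulators (21.6), 13 of 23 genes of H3.3 and its chaperones (11.8), 12 of 25 late-response (7.41) and 5 of 25 housekeeping genes (7.07). Among markers it was 14 of 21 for neurons (12.6), 11 of 20 for interneurons (10.4), 11 of 20 for astrocytes (8.97), 15 of 24 for the oligodendrocyte lineage (11.6), 10 of 18 for microglia (7.90) and 10 of 17 for endothelium (10.6). Of olfactory and vomeronasal receptors 132 of 1469 had one (163). Of the immediate-early genes 6 of 31 did (6.86), Fosl2, Atf3, Nr4a3 and Homer1 with gained and Fosl1 and Dusp5 with lost regions first by adjusted p, though Homer1 and Dusp5 had regions of both directions. None of these counts passed (permutation, smallest adjusted p = 0.206, for channel genes), and direction passed in no group. The test against genes of the 7 lists is not used here, since 9124 of those 9790 genes had a CATCH-IT region. The share gained was 57.3% (exact 95% interval 56.8 to 57.7, exact binomial p = 7.60e-246), and promoters held 5.17% of gained and 5.04% of lost regions. As 1 read stood for up to 2.72 in KCl and up to 1.39 in control libraries, depth may bear on this split, which was not tested. In 51801 regions every library of one group was at 0, and 46.2% of regions were exactly 380 bp long, against 0.0430% in the H3.3 lists together. The name of this deposited table carries a duplicate setting of 6. KCl and control libraries were on separate lanes.

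**Figure D3:**
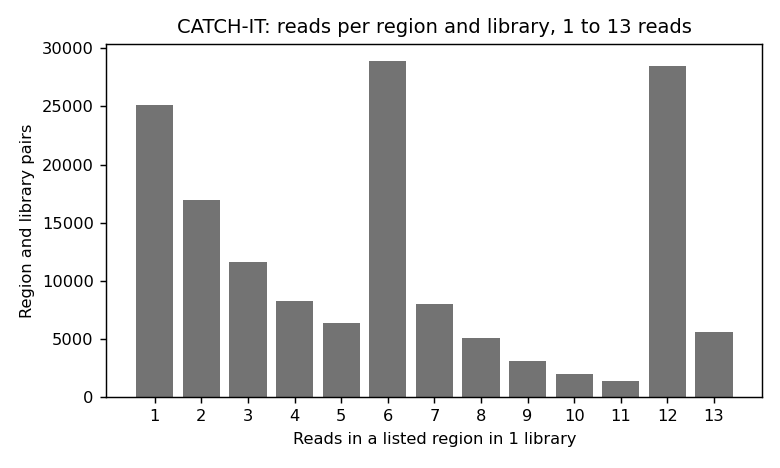
Number of region and library pairs of the CATCH-IT list by reads in the region, for 1 to 13 reads. The counts of 6 reads (28934 pairs) and 12 reads (28472 pairs) stood above those of 5 and 7 reads (6372 and 7982) and of 11 and 13 reads (1336 and 5578).

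In NeuN-positive hippocampal nuclei, enriched housing went with gained H3.3 at 1151 regions and lost H3.3 at 455 regions with an authors' adjusted p of 0.05 or less, of 1642 listed. H3.3 rose at Kazn from 8.14 ± 3.01 to 36.8 ± 1.22, at Plcg2, a phospholipase, from 7.88 ± 0.488 to 32.0 ± 1.97, and at Nfatc1, a calcium-regulated transcription factor gene, from 11.4 ± 1.27 to 44.4 ± 7.11. It rose also at Syce1l and Ddah1, and at 1 region of Ptprg, which had 2 lost regions besides. It fell at Ift52, a gene of intraflagellar transport, from 17.5 ± 1.36 to 2.49 ± 1.31, at Ube2f, a gene of protein neddylation, from 18.3 ± 0.297 to 2.81 ± 1.56, and at Slc38a2, an amino acid transporter gene, from 23.4 ± 3.25 to 5.78 ± 1.51. Fgf14, Clmp and Mboat2 fell too. The log2 fold changes of Kazn and Fgf14 in the authors' deposited table were 2.18 and -3.00, with adjusted p of 0.000853 and 0.0124. The Kazn region was on chromosome 4 from 141692661 to 141693000 (mm9), and the Fgf14 region on chromosome 14 from 124889341 to 124889540, both in introns.

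In NeuN-positive nuclei 8 voltage-gated channel genes had 4 gained and 10 lost regions, against 69.1% gained among other genes, which did not pass (Fisher's exact test, adjusted p = 0.104). With 1 region per gene it was 3 gained and 5 lost (Fisher's exact test, adjusted p = 0.535). Kcnma1, a calcium-activated potassium channel gene, fell from 18.6 ± 2.82 to 4.46 ± 1.46 and Kcnh1 from 25.6 ± 4.24 to 7.28 ± 3.03. All 3 presynaptic genes fell, Bsn from 24.1 ± 6.42 to 6.99 ± 1.01, Rims2 and Erc1 (Fisher's exact test on direction, adjusted p = 0.599). The receptor genes Grm8, Gabbr2 and Gabrg3 rose. Magi2 rose and Homer2 fell among postsynaptic genes, and 5 gained and 6 lost regions lay at adhesion genes. Nfatc1 and Mef2b rose and Smarca4 fell among activity-linked regulators. Markers of other cells rose as well, with 4 oligodendrocyte lineage genes (Mbp, Myrf, St18, Lhfpl3), 3 endothelial genes (Cdh5, Ebf1, Tie1) and 2 astrocyte genes (Aldh1l1, Gpc5), and none fell, while 68.3% of regions of genes outside the oligodendrocyte list were gained (Fisher's exact test, adjusted p = 1). Dlx5 and Adarb2 rose and Erbb4 fell among interneuron markers, and Olfr1104 and Olfr446 rose among receptors of smell. No immediate-early, late-response, neuron, microglia or housekeeping gene, and no gene of H3.3 or its chaperones, was listed. Each of these lists had at most 14 members with a region in any table, and 839 of 9790 genes were named here. Such zeros carry little information.

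The share gained in NeuN-positive nuclei was 71.8% (exact 95% interval 69.6 to 74.0, exact binomial p = 5.36e-72). Intergenic places held 47.2% of gained and 37.8% of lost regions (Fisher's exact test, adjusted p = 0.00651) and gene bodies 41.0% and 49.0% (adjusted p = 0.0175). The split turned with GC content, from 41.0% gained in the lowest part to 96.9% in the highest. Relative to input 100% of the 1642 regions moved the same way as in count, and 95.5% by at least 2-fold. No lane held libraries of both groups.

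**Figure D4:**
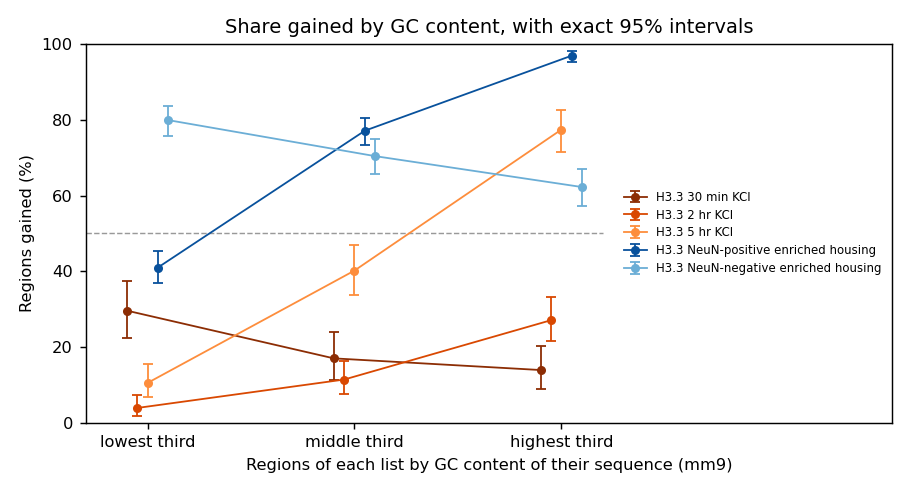
Percent of regions gained in the 5 H3.3 lists, each split into 3 parts by GC content of the region, with exact 95% binomial intervals; the dashed line marks an even split. The 5 hr list ran from 10.5% to 77.4% and the NeuN-positive list from 41.0% to 96.9%, while the other lists stayed on one side of the line.

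In NeuN-negative nuclei, enriched housing went with gained H3.3 at 844 regions and lost H3.3 at 350 regions with an authors' adjusted p of 0.05 or less, of 1196 listed. H3.3 rose at Fam98b from 2.66 ± 0.741 to 13.6 ± 0.966, at Dscam, an adhesion gene, from 0.317 ± 0.548 to 8.20 ± 4.03, and at Celf4, an RNA-binding protein gene of neurons, from 0.830 ± 0.914 to 9.96 ± 5.10. It rose also at Tcf20, listed at 0 in normal housing. It fell at Lpp from 10.5 ± 1.84 to 0.747 ± 0.648, and at Dlg2 from 9.34 ± 1.15 to 1.24 ± 1.33. Rac2, Clns1a and Ccr9 fell and were listed at 0 in enriched housing. The log2 fold changes of Fam98b and Lpp in the authors' deposited table were 2.35 and -3.81, each with an adjusted p of 0.00201. The Fam98b region was on chromosome 2 from 117078441 to 117078800 (mm9), and the Lpp region on chromosome 16 from 24472381 to 24472660, both in introns.

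Of 25 presynaptic genes 7 had a NeuN-negative region (Fisher's exact test, adjusted p = 0.0125), with Erc1, Rims4, Syn3, Syt2 and Unc13c up and Bsn, from 11.1 ± 1.86 to 2.38 ± 0.239, and Sv2c down. Of 57 adhesion genes 13 had one (Fisher's exact test, adjusted p = 0.000991), 9 up and 4 down. Neither count passed against random lists of the same gene lengths. The neuron markers Celf4, Elavl2, Ndrg4 and Stmn2 rose and none fell in these NeuN-negative nuclei (Fisher's exact test on direction, adjusted p = 0.953). Among microglia markers C1qa, a complement gene, rose from 0.527 ± 0.469 to 6.39 ± 1.35 and P2ry12, a purine receptor gene, fell from 6.96 ± 0.785 to 0.747 ± 0.648. The astrocyte markers Gpc5 and Plcd4, the interneuron marker Adarb2 and the glutamate receptor gene Grik2 rose. Gabrb1 rose and Gabrg3 fell, Kcnip4 and Crebbp fell, and Kcnn2 and Magi2 had regions of both directions. Among olfactory and vomeronasal receptors Vmn1r46 rose and Olfr1053 and Olfr644 fell. No immediate-early, late-response, oligodendrocyte, endothelial or housekeeping gene was listed. Each of these lists had at most 16 members with a region in any table, and 586 of 9790 genes were named here, so these zeros carry little information. The share gained was 70.7% (exact 95% interval 68.1 to 73.3, exact binomial p = 7.78e-48), 1.07 points below NeuN-positive nuclei (Fisher's exact test, adjusted p = 0.667), and 50.8% of gained against 39.4% of lost regions were intergenic (adjusted p = 0.00651). Here 1 read stood for 1.16, 2.64 and 0.542 in enriched housing libraries and for 0.948, 0.676 and 0.904 in normal housing libraries. Whether this difference in depth set part of the split was not tested. Of 1101 regions with finite ratios to input, 99.8% moved the same way relative to input and 95.2% by at least 2-fold. Lane and housing coincided in this comparison.

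Across time points the share of gained H3.3 regions differed between 30 min and 2 hr by -5.76 points (Fisher's exact test, adjusted p = 0.0180) and between 2 hr and 5 hr by 29.9 points (adjusted p = 6.71e-34). Lane and treatment coincided at 30 min and 2 hr but not at 5 hr, so the last difference is also one of lane layout. No region overlapped between any of the 3 time points, where random placement gave 0.045 to 0.073 overlaps, so that 0 carries little information. For overlap of at least 1 bp over all 21 pairs of lists, the placement test by permutation gave 0 overlaps beyond chance, with 0 also at an unadjusted p under 0.05 (smallest adjusted p = 1). Within 1000 bp, 4 regions of 30 min lay near a 5 hr region against 0.316 at random (permutation adjusted p = 0.0210). Of these, 3 were lost at both times and 1 was lost at 30 min and gained at 5 hr. Of the 667 H3.3 regions at 5 hr, 6 overlapped a CATCH-IT region against 8.09 at random, and 26 NeuN-positive regions did so against 19.8. Direction at overlapping regions was tested in 3 pairs with at least 10 overlaps. The highest share was 83.3% in the same direction over 12 overlaps of CATCH-IT and NeuN-negative regions (Fisher's exact test, adjusted p = 0.136).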

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

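Of the tests given here, those chosen only after the result was seen were the ones of read stacks, of overlap as a sign of shared turnover, of sequencing lanes, of GC content within single lists, and of a GC bias in input as the whole cause. Differences in the share of gained regions between comparisons were picked out because Fisher's exact test of the difference itself passed. By Fisher's exact test they were -5.76 points from 30 min to 2 hr, 29.9 points from 2 hr to 5 hr, 24.1 points from 30 min to 5 hr (adjusted p = 5.99e-17), and 13.03 points from H3.3 to CATCH-IT at 5 hr (adjusted p = 4.52e-11). At 30 min and 2 hr lane and group coincided, while at 5 hr 3 lanes held libraries of both groups, so the differences against H3.3 at 5 hr cannot be told apart from lane layout. The lists were normalised separately, and 647 of the 667 regions at 5 hr had an authors' adjusted p above 0.05. Among regions with an adjusted p of 0.05 or less, an alternative chosen after the data were seen, the last difference was 2.26 points and did not pass (Fisher's exact test, adjusted p = 0.826), while the others passed.

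CATCH-IT regions were nearly all present in one group and at 0 in the other, 96.5% of gained and 99.4% of lost regions. A signal at gene starts is argued against, since regions within 3000 bp of a gene start were 1.08 times as frequent as at random places. Overlap with the H3.3 regions of 5 hr was 0.742 times random, and an overlap above the upper 95% bound of 1.61 is argued against. This cannot decide on turnover, since 647 of those 667 regions had an authors' adjusted p above 0.05. That list also holds changes in count of about 3-fold or more, not turnover. Reads stacked at single positions may account for many regions, since a single position seen by 200 bp windows moved by 20 bp gives 380 bp, the length of 46.2% of regions, 60.8% of gained and 26.7% of lost ones. Counts of exactly 6 reads were 4.03 times the mean of their neighbours, and 1573 gained and 2005 lost regions had 6 reads in each of the 3 libraries of their group. The name of this table carries a duplicate setting of 6, so a limit on reads per position could set these counts, and they do not give the height of the stacks. Lane and treatment cannot be told apart, as 0 lanes held libraries of both groups, and turnover stays open.

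Most H3.3 regions were lost after 30 min and 2 hr of KCl, and most were gained after enriched housing. The planned test by GC content left it open, since the majority direction held in all 3 GC classes in 3 of 4 lists. Taken singly, GC content is argued against as the whole cause at 30 min, 2 hr and in NeuN-negative nuclei, where 3 of 3 lists kept their direction in each GC class, but in NeuN-positive nuclei only 41.0% were gained in the lowest class, so GC content may set part of that split. A GC bias shared with input is argued against as the whole cause there, since 95.5% of regions (lower exact 95% bound 94.4) moved the same way by at least 2-fold relative to input. The ratio holds the count on which regions were listed, which favours such agreement. Whether a GC bias shared with input sets a part stays open. The implied log2 input ratio was 0.21 higher in the highest than in the lowest class, between the bounds set in advance. Lane and group cannot be told apart, as 0 lanes held libraries of both groups over the 4 lists, and depolarisation and housing stay open as untested biological explanations. Depth per library was not tested as a cause either, and it could not be read for the enriched NeuN-positive libraries.

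Few H3.3 regions lay on the X chromosome, 1, 2, 5, 1 and 1 regions in the 5 lists from 30 min to NeuN-negative nuclei, although it holds 6.34% of bases. Lower gene density is argued against, since places of the same mix of gene starts, gene bodies and intergenic sequence gave an X share at least 7.65 times the observed one. Halved read counts on a single X copy may account for it, because at most 3.27% of autosomal regions in any of the lists had a higher group mean of 2 times the first percentile or more, so few would stay listed at a halved count. In the CATCH-IT list 59.5% of autosomal regions had such a mean, and 3.00% of regions lay on X, 0.473 times its share of bases. Regions on Y were listed at 30 min (2) and in CATCH-IT (24) only. The sex of the animals is not given in the labels, whether sexes were mixed is not known, and no biological explanation was tested.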

How the results depend on the processing

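Alternatives with an adjusted p of 0.05 or less and with CATCH-IT regions over 380 bp only were chosen after the data were seen. Of the values for main results under alternatives set in advance, 59 counts of regions stayed within 1.5-fold and 16 moved; of the other values 74 stayed (direction and side of the threshold, or within 1.5-fold for counts), 6 moved, 6 weakened and 2 turned. What limits these results is that regions under about 3-fold are not listed, that few regions have high counts, and that the authors' adjusted p cannot be recomputed without a library; where counts of regions dropped, fewer regions entered by construction. No paired analysis was possible because the packed values carry no library names, although at 5 hr the labels put 1 KCl and 1 control library on each of 3 lanes.

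With an adjusted p under 0.01, 11 regions stayed at 30 min (18.2% gained, exact binomial p = 0.0654), 17 at 2 hr, 1 at 5 hr (0% gained), 2 for H3.1/2 and 9 in NeuN-positive nuclei. With an absolute log2 fold change over 2, 149, 315 and 233 regions stayed at 30 min, 2 hr and 5 hr, 0 for H3.1/2 and 568 in NeuN-positive nuclei. With a higher group mean of at least 20, 3 regions stayed at 30 min and 3 at 2 hr (0% gained in each), 11 at 5 hr (54.5% gained, turned), 1648 for CATCH-IT (99.5% gained, fixed largely by the filter, as 1 read counted up to 2.72 in KCl and up to 1.39 in control libraries), 827 in NeuN-positive nuclei and 2 in NeuN-negative nuclei (0% gained, turned), and 1 difference in share passed in place of 4, that with CATCH-IT, which rests on the same filter. With an adjusted p of 0.05 or less, 20 regions stayed at 5 hr (55.0% gained, turned) and 4 for H3.1/2.

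Leaving out one library in turn gave 17.4 to 23.8% gained at 30 min, 13.7 to 16.2% at 2 hr, 40.0 to 46.7% at 5 hr, 50.0 to 80.0% for H3.1/2, 57.1 to 57.3% for CATCH-IT, 67.8 to 76.9% in NeuN-positive and 70.5 to 71.2% in NeuN-negative nuclei. At 5 hr the split no longer passed without the second KCl value (46.2%, exact binomial p = 0.0697) or the third (46.7%, p = 0.12); the cause was not tested.

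Length-matched lists left 0 of 6 gene list counts (12 at an unadjusted p under 0.05 among 126 permutation tests), and promoters alone left 0 of these 6. With promoters alone 1 other count passed, in CATCH-IT, against a background made mostly of CATCH-IT genes, so it is not read as enrichment. Under the stricter adjusted p, 1 feature difference passed in place of 5 and 1 agreement in direction in place of 0 (over 1 test, not 3), and the gene body difference turned to 16.7 points at 30 min and -100 for H3.1/2, from few regions. Overlap within 1000 bp passed for 1 pair, 30 min and 5 hr, with 4 regions (permutation adjusted p = 0.0210). It crossed the random mean, without passing, for 2 hr and 5 hr (1), 5 hr and NeuN-negative (2), NeuN-positive and NeuN-negative (2), and CATCH-IT with 2 hr (35), 5 hr (43) and NeuN-negative (70). Overlap of at least 50% of the shorter region crossed it at 30 min for CATCH-IT (4) and NeuN-positive (0), and CATCH-IT regions over 380 bp for 2 hr (0), 5 hr (1), NeuN-positive (1) and NeuN-negative (1). The cause was not tested.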

Other observations

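The comparison of genes shared between lists was chosen after the lists were seen. Some pairs of lists shared more genes than random lists of the same gene lengths, 5 of 10 pairs after adjustment, and others did not. Genes with H3.3 regions at both 2 hr and 5 hr numbered 45 against 24.3 at random, 1.85 times as many (permutation p = 1e-04, the smallest these permutations can give, adjusted p = 0.001). Genes shared by 30 min and 2 hr numbered 33 against 19.5 (permutation adjusted p = 0.00525), those shared by 5 hr and NeuN-positive nuclei 59 against 40.6 (adjusted p = 0.00525), and those shared by 30 min and NeuN-negative nuclei 39 against 25.2 (adjusted p = 0.00525). Those shared by NeuN-positive and NeuN-negative nuclei numbered 68 against 54.5 (permutation adjusted p = 0.0472), and those shared by 30 min and 5 hr, 22 against 18.3, did not pass (adjusted p = 0.286). Direction at shared genes passed in 0 of 10 pairs, and in 1 at an unadjusted p under 0.05 (Fisher's exact test).

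Genes listed at all 3 time points numbered 9. Among them, Dlg2, a postsynaptic scaffold gene, Dab1, of the reelin pathway, Limch1, Ptprn2 and Ptprd, a receptor phosphatase, were listed as lost each time, and Ptprd and Ptprn2 also had a gained region at 2 hr. Ephb1, an ephrin receptor gene, was listed as gained each time, as were regions assigned to Fgfr2. Schip1 was listed as gained at 30 min and 2 hr and lost at 5 hr. The log2 fold changes of Dlg2 in the authors' deposited table were -2.28, -2.10 and -1.67, and those of Ephb1 were 2.05, 1.98 and 2.05. The regions of Dlg2 started at 99103361, 98955161 and 99334881 on chromosome 7 (mm9), at different places of this long gene. Those of Fgfr2 started at 137981101, 139531561 and 137365601 on the same chromosome, over 2 Mb of a very long annotated gene. Their assignment to Fgfr2 rests on that annotated span, so a repeated gain at this gene is not shown. The adjusted p at 5 hr in the authors' deposited table was above 0.05 for all 9, from 0.0692 for Ptprn2 to 0.3001 for Schip1.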
